A study of Mus musculus with 5 samples.

How the data were processed

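Reduced representation bisulfite sequencing was done on 5 mouse samples with 1 library each: female ESC, pESC, PGC, ESC-PGCLC and pESC-PGCLC. Per the submitters' processing notes, reads were handled with Bismark 0.16.3 and Bowtie2 on the build mm10; the role of each tool, the trimming and any coverage filter are not given in the sources used here. The deposited values are a fraction from 0 to 1, the methylation level per region, with the region class and the cytosine context (CG, CHG or CHH) beside it. The 8 region classes are CGIs, CGI shores, promoters, 5' UTRs, exons, introns, 3' UTRs and repeats, as the deposited files name them; how these regions were drawn is not given in the sources used here. Levels are printed as percent, 100 times the deposited fraction.

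The plan, fixed before the data were examined, assumed read counts per CpG site: at least 10 reads per site, 1 kb windows, Fisher's exact tests, Wilson intervals and a comparison of strands. The deposited values hold no read counts, coverage, strand or single sites, so none of these could be applied, and depth and counting error are unknown. The level of a region was used as deposited, and a region was called different between 2 libraries at a difference of at least 25 percentage points, the size threshold of the plan, with no test. CGIs took the place of windows. A region entered a comparison when all 5 libraries listed it. Differences compare 2 libraries, not 2 conditions. The difference of the 2 induction changes was counted at CGIs and promoters, at 25 and 40 points.

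CGIs and shores carry coordinates, given as in the deposited files, whose counting base is not stated. Promoter, exon, intron and UTR entries carry Ensembl gene IDs, which were paired with 0 symbols by the reference table used here; promoters are therefore reported as counts and means. Repeat entries carry a family name and a position in its consensus, with no genomic position. Genes were tied to regions through RefSeq coordinates of the matching assembly, which give no strand: the longest CGI overlapping either end of a gene within 1000 bp was used, or the longest shore where there was no CGI. This rule was set after values had been seen. It gave a region to 12081 of 21900 protein-coding genes, 11140 of them a CGI. Windows of paternally methylated regions were those of the plan, with strands of the 4 genes from general knowledge. Of the maternally methylated genes, Mest, Snrpn and Impact had no region by this rule, and of the paternally methylated, H19 and Zdbf2 had none.

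Named genes follow a rule fixed before the data were examined: all measured members of the imprinted lists, up to 10 called regions with a gene symbol in each direction, and up to 4 members of each gene list with the largest absolute difference. Promoters could not be named, so the rule was applied to CGIs, and its part asking for 5 CpG sites was not applied. Gene models and CGIs with no gene, named beside small counts, were chosen after their values were seen. Gene lists comprised maternally and paternally methylated imprinted regions, germline genes, PGC specification genes, pluripotency genes, primed epiblast genes, DNA methylation machinery, fibroblast (feeder) genes, gonadal somatic genes, trophoblast genes, Hox genes, Rhox genes, clustered protocadherins and X-linked genes. Neighbouring protocadherin genes can share 1 region, as Pcdhb15 and Pcdhb16 do, which the random lists below do not reproduce. For each list the median difference was placed as a percentile among 10000 random lists with as many genes from each of 10 bins of mean methylation over the 5 libraries. The highest bin ran from a mean of 3.10% to 82.8%, so lists of methylated genes were matched loosely; in an alternative each member was matched to the 50 genes nearest in mean methylation, and its percentile is given where it moved into or out of the central 95%, and for germline genes in every comparison. Genes are not replicates, and the percentile describes these libraries only. Called CGIs are said to lie at an imprinted gene when they lie within 1000 bp of, or inside, a measured maternally methylated gene, Snrpn, or Gnas, Inpp5f, Impact, Grb10 or Mest, the last 5 added after values had been seen.

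The threshold and the list percentile were tested on simulated libraries with 200 regions raised by 40 points and 50 reads assumed per region. For pESC against female ESC the call found 98% of the changed CGIs among 14214, with 3 unchanged CGIs called, and 95% of the changed promoters among 20388, with 50 unchanged promoters called. Across all comparisons, between 2 and 5 unchanged CGIs and between 43 and 55 unchanged promoters were called. At 50 reads per region, promoter counts of that size can thus arise with no change. The 50 reads are an assumption, so these numbers do not measure the error of the deposited levels. Of 100 simulated lists of 17 methylated CGIs with no change of their own, among 14214 CGIs that all lost the same share, 16 lay outside the central 95% with 10 bins and 6 with matching to the nearest CGIs. Alternatives were thresholds of 10 and 40 points, autosomes only, regions common to the 2 libraries compared and, chosen after seeing the data, a correction for the mean CHH level of the library, leaving out regions at exactly 0 or 1, taking out the overall shift of the class (the ratio of the 2 class means), other imprinted members, matching lists on region length too, and matching on the genes nearest in mean methylation. Bootstrap intervals used 1000 resamples over regions. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used, with random seed 7.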

Results

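CpG methylation was measured by reduced representation bisulfite sequencing, an assay that reads cytosine methylation in the CpG-rich part of the genome after restriction digestion, in 5 mouse libraries of the C57BL6 strain. The groups were female embryonic stem cells (female ESC), parthenogenetic embryonic stem cells (pESC), which derive from an egg with no sperm genome, primordial germ cells (PGC) sorted with SSEA1 beads from fetal gonads at embryonic stage E12.5, of a sex not given in the sources used here, and primordial germ cell-like cells induced from each stem cell line (ESC-PGCLC and pESC-PGCLC). Induction passed through 46 h of epiblast-like culture and 4 days of germ cell-like culture, after which cells carrying both CD61 and SSEA1 were sorted. Each group had 1 library, so no difference reported here has a replicate error or a p-value. CpG levels were listed for between 157458 regions and repeats (female ESC) and 168945 (ESC-PGCLC), and 154711 were listed in all 5 libraries. Read depth is unknown, since the files give levels without read counts.

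Mean methylation was highest in female ESC and lowest in PGC in each of the 8 region classes. Outside CpG islands (CGIs) and 5' UTRs, pESC came next, followed by ESC-PGCLC and pESC-PGCLC; in 5' UTRs ESC-PGCLC (4.54%) was slightly above pESC (4.52%), and in CGIs both ESC-PGCLC (3.67%) and pESC-PGCLC (3.59%) were above pESC (3.55%). These 3 differences turned when the mean non-CpG (CHH) level was taken out, to -0.125 points in 5' UTRs and -0.0301 and -0.0848 points in CGIs. Over 20388 promoters the mean level was 17.2% in female ESC, 15.9% in pESC, 15.4% in ESC-PGCLC, 14.6% in pESC-PGCLC and 13.8% in PGC. Repeats followed the same order, with means of 50.2%, 46.3%, 45.3%, 43.2% and 40.8% over 46641 repeat entries. LINE/L1 elements, the main autonomous retrotransposons of the mouse, had a mean of 55.1% in female ESC and 45.5% in PGC, and LTR/ERVK elements, a class of endogenous retroviruses, had 54.3% and 45.1%. CGIs were almost free of methylation in every library, with medians between 1.48% (PGC) and 1.65% (pESC-PGCLC) over 14214 islands. Non-CpG cytosines, a measure of unconverted or non-CpG methylated bases, stood between 0.592% (pESC) and 0.741% (ESC-PGCLC) in promoters in the CHH context.

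**Figure D1:**
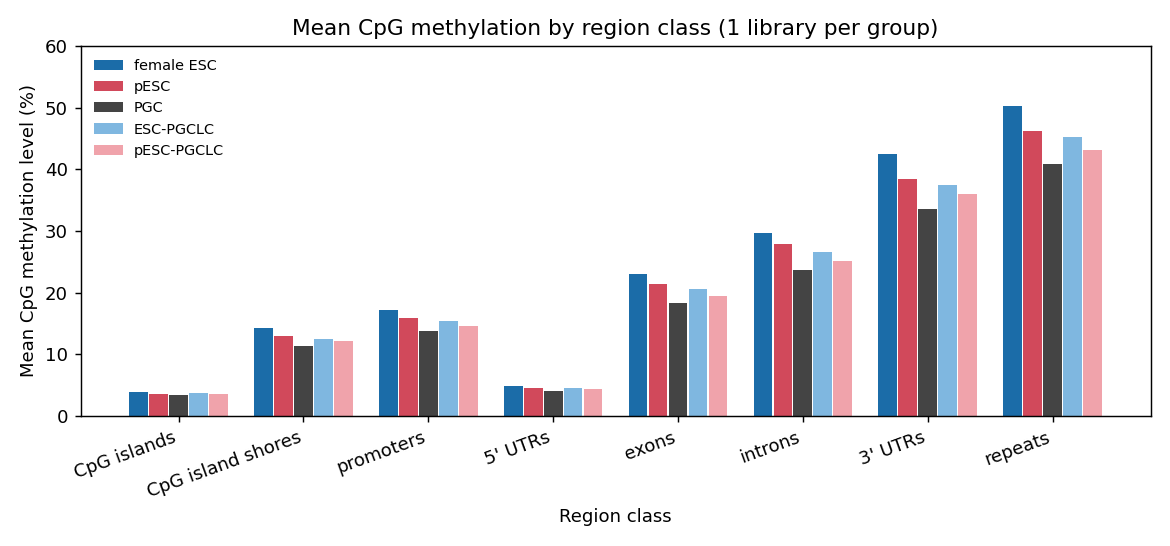
Bars give the mean CpG methylation level (vertical axis, %) of each region class (horizontal axis) over the regions listed in all 5 libraries, 1 bar per library and 1 library per group. Repeats were the most methylated class, from 50.2% in female ESC to 40.8% in PGC, and CGIs the least, from 3.91% in female ESC to 3.41% in PGC.

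The comparison of pESC with female ESC asked how a genome of maternal origin alone differs from a biparental one. Islands of genes subject to genomic imprinting, in which methylation marks the allele inherited from one parent, were far more methylated in pESC. Of 15 genes listed with maternally inherited methylation, 12 had a measured region, and 11 of these 12 were higher in pESC, 8 of them by at least 25 percentage points. Their median level was 41.0% in pESC and 11.9% in female ESC. The median difference of 31.4 points lay above every one of 10000 random lists matched on mean methylation, whose median was -1.44 points; its bootstrap 95% interval over members was 16.7 to 40.1 points.

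Airn, the noncoding RNA that silences Igf2r in cis, had the largest difference: its island at chromosome 17, 12741440 to 12742489 (mm10), inside the Igf2r gene, had a level of 61.2% in pESC and 2.01% in female ESC. Kcnq1ot1, the antisense RNA of the Kcnq1 domain, was at 67.7% against 16.7% (chromosome 7, 143295404 to 143295824). Peg13, a noncoding RNA gene within Trappc9, was at 77.8% against 36.9%, and Zrsr1, an intronless gene within Commd1, at 41.0% against 1.60%. The island shared by Peg10, a retrotransposon-derived gene needed for placenta formation, and its neighbour Sgce was at 39.1% in pESC and 3.25% in female ESC. Nap1l5 was at 56.1% against 22.8%, Peg3, which encodes a zinc finger protein, at 65.7% against 36.2%, and Plagl1, another zinc finger gene, at 28.7% against 1.35%. Smaller differences were seen at Gnasas1, the antisense RNA of the Gnas locus (40.9% against 17.8%, on an island shore), Nnat (25.5% against 15.1%) and Mcts2 (6.14% against 1.53%). The shore at Slc38a4, which encodes an amino acid transporter, was the exception, with 3.74% in pESC and 8.61% in female ESC.

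Further regions of 5 imprinted genes, chosen after their values were seen, were of 2 kinds. The pair of islands within Gnas at chromosome 2, 174297262 to 174297532 and 174298463 to 174300644, had 64.4% and 58.4% in pESC against 18.9% and 19.7% in female ESC. The island within Impact was at 49.4%, 30.4 points above female ESC, that within Inpp5f at 48.6% against 26.1%, that within Grb10 at 20.5% against 1.74%, and the shore within Mest at 53.7% against 6.59%. The other 4 islands of these genes were not higher to that degree: a pair at Gnas had 2.77% and 3.15% in pESC against 2.08% and 2.99%, the other island of Grb10 had 1.59% against 1.84%, and that at the end of Inpp5f had 12.0% against 16.1%.

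**Figure D2:**
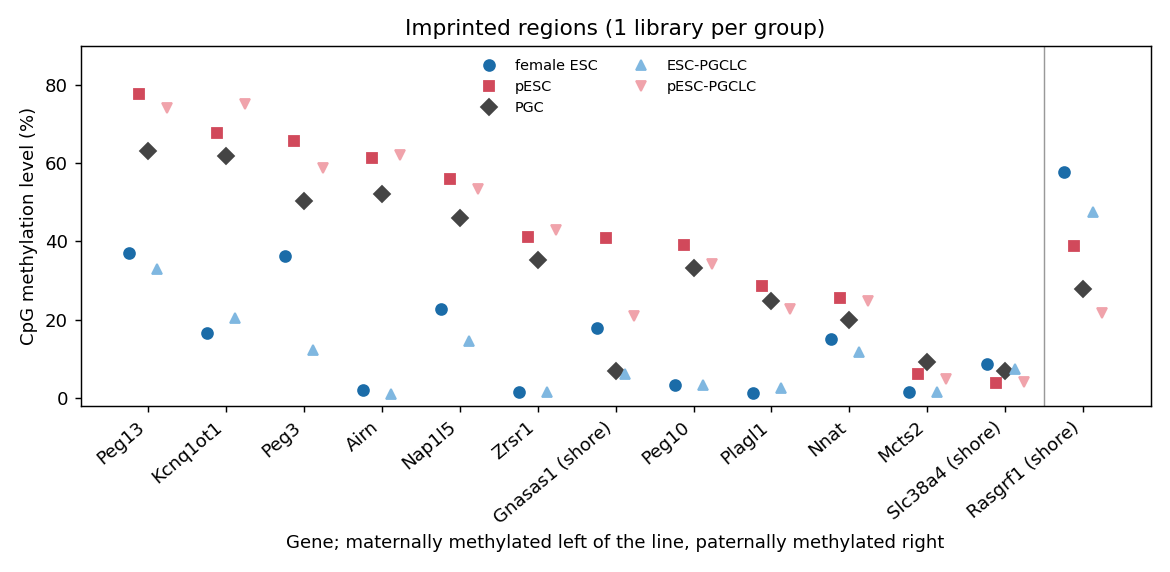
Points give the CpG methylation level (vertical axis, %) of each measured imprinted region (horizontal axis, by gene), 1 point per library and 1 library per group. The line separates regions listed as maternally methylated from those listed as paternally methylated. At Airn the points of pESC, PGC and pESC-PGCLC lie at 61.2%, 52.1% and 62.1%, and those of female ESC and ESC-PGCLC at 2.01% and 1.03%.

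Across all 14214 islands, 14 were at least 25 points higher in pESC and 4 were at least 25 points lower. Of the 14, 12 lay at imprinted genes, among them the pair within Gnas and the island within Impact, genes added after values were seen. The other 2 were an island within Polrmt, the mitochondrial RNA polymerase gene (52.2% in pESC, 21.1% in female ESC), and a 292 bp island at Sil1, which encodes a chaperone cofactor of the endoplasmic reticulum (33.3% against 2.52%). The islands lower in pESC were at chromosome 13, 119836757 to 119837075, with no gene at it (13.8% against 57.7%), within Clstn2, a calsyntenin gene (49.3% against 80.3%), at Trim52 (36.2% against 63.4%), and at chromosome 18, 3864086 to 3864324, with no gene at it (29.4% against 54.9%). Of these 4, 3 were no longer than 400 bp. When the overall shift of the island class was taken out as 1 factor, 14 islands were higher and 1 was lower. At a threshold of 10 points the balance was the opposite, with 27 islands higher and 128 lower. Among promoters, 39 were at least 25 points higher and 54 lower in pESC, or 41 higher and 30 lower with the overall shift of the class taken out.

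Germline genes, many of which have promoters methylated in somatic cells, were lower in pESC at 14 of 17 measured members, with list medians of 27.3% in pESC and 31.0% in female ESC. The median difference of -5.14 points lay at percentile 0.13 of the random lists drawn from bins of mean methylation, but at percentile 26.9 when each member was matched to the 50 genes nearest in mean methylation. Of the 382 CGIs with a mean of at least 30%, 90.3% were lower in pESC. Mov10l1, a piRNA pathway helicase gene, was at 57.3% in pESC and 68.0% in female ESC, Tuba3a, a testis tubulin gene, at 37.1% against 47.3%, Hormad1, a meiotic chromosome axis gene, at 14.7% against 23.6%, and Mael, a transposon-silencing gene, at 22.5% against 31.0%. Clustered protocadherins, cell-adhesion genes of neurons, were lower at 19 of 25 members (median difference -1.68 points, percentile 3.39), with Pcdha8 at 36.4% against 46.2%. X-linked genes had a median of 1.49% against 1.54% over 319 members (percentile 0.75).

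Lists of developmental regulators were almost unmethylated in both lines. List medians in female ESC were 1.70% for 5 PGC specification genes, 1.35% for 8 pluripotency genes, 1.86% for 6 primed epiblast genes, 1.27% for 8 genes of the DNA methylation machinery, 1.94% for 6 fibroblast (feeder) genes, 1.44% for 9 gonadal somatic genes, 1.36% for 5 trophoblast genes and 1.79% for 37 Hox genes. Their median differences in pESC lay between percentiles 10.8 (primed epiblast genes) and 93.5 (Hox genes) of the random lists. The largest differences in these lists were at the shores of Nr5a1, the gonadal and adrenal nuclear receptor (64.0% in pESC against 77.8% in female ESC), Hoxd4 (39.8% against 50.5%) and Tcf21 (36.3% against 46.2%), at the island of Hoxb1, which was higher in pESC (10.2% against 3.67%), and at the shore of Dnmt3l, the cofactor of de novo methylation (33.7% against 39.0%). Of 3 measured Rhox genes, homeobox genes of the X chromosome, 2 were higher and 1 lower in pESC (list percentile 91.3), the lower one being Rhox13, at 24.5% against 38.4%.

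The comparison of ESC-PGCLC with PGC asked how close germ cell-like cells from a biparental line come to germ cells of the fetus. Imprinted islands were much lower in ESC-PGCLC: 11 of 12 maternally methylated members were lower, 7 by at least 25 points, with medians of 6.75% in ESC-PGCLC and 34.1% in PGC (median difference -30.0 points, below all 10000 random lists). Airn was at 1.03% in ESC-PGCLC and 52.1% in PGC, Kcnq1ot1 at 20.5% against 61.7%, Peg3 at 12.2% against 50.3%, Zrsr1 at 1.61% against 35.1%, Nap1l5 at 14.5% against 46.0%, Peg13 at 33.0% against 63.2% and Peg10 at 3.22% against 33.1%. Plagl1 was at 2.47% against 24.8%, Nnat at 11.7% against 19.9% and Mcts2 at 1.39% against 9.22%, while Gnasas1 (6.18% against 6.78%) and Slc38a4 (7.33% against 6.74%) differed by under 1 point.

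Outside imprinted islands ESC-PGCLC was the more methylated library. The mean over promoters was 15.4% in ESC-PGCLC and 13.8% in PGC, and the mean over repeats 45.3% against 40.8%. Germline genes were higher in ESC-PGCLC at 15 of 17 members, with medians of 30.4% and 23.2% (percentile 99.97, but 91.6 with matching to the nearest genes), where 15.4% of the CGIs with a mean of at least 30% were lower. Dpep3, a testis dipeptidase gene, was at 69.2% in ESC-PGCLC and 54.4% in PGC, Mov10l1 at 63.2% against 49.1%, Tuba3a at 42.5% against 30.6%, and Sycp1, a component of the synaptonemal complex, at 32.5% against 23.2%. X-linked genes were lower in ESC-PGCLC, with a median of 1.63% against 2.32% in PGC, below all random lists. Among gonadal somatic genes, Nr5a1 was at 70.2% in ESC-PGCLC and 56.3% in PGC and Tcf21 at 35.0% against 23.7% (list percentile 83.4).

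By island, 1 was at least 25 points higher in ESC-PGCLC (Ppp1r2-ps5, chromosome 17, 6493954 to 6494314, 69.6% against 39.6%) and 12 were lower. Among islands common to these 2 libraries 5 were higher and 13 lower. Of the 12, 9 lay at imprinted genes, among them the pair within Gnas, a gene added after values were seen. The other 3 lay within Prrc1 (8.21% against 34.5%), Kdm2b, a histone demethylase gene (17.4% against 43.4%), and Rapgef2 (10.7% against 35.7%), and each was no longer than 400 bp. At a threshold of 10 points this balance was the opposite, with 114 islands higher and 43 lower in ESC-PGCLC. Among promoters 33 were higher and 21 lower by 25 points, or 15 higher and 28 lower with the overall shift of the class taken out.

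The comparison of pESC-PGCLC with PGC put the parthenogenetic germ cell-like cells beside the same fetal germ cells. Here no imprinted member differed by 25 points: 9 of 12 were higher and 3 lower in pESC-PGCLC, with medians of 38.7% and 34.1% (median difference 7.64 points, above all random lists, with a bootstrap 95% interval over members of -0.468 to 10.5). Gnasas1 was at 21.1% in pESC-PGCLC and 6.78% in PGC, Kcnq1ot1 at 75.0% against 61.7%, Peg13 at 74.2% against 63.2%, Airn at 62.1% against 52.1%, Peg3 at 58.8% against 50.3%, Zrsr1 at 43.0% against 35.1%, Nap1l5 at 53.4% against 46.0%, Nnat at 24.8% against 19.9% and Peg10 at 34.3% against 33.1%. Plagl1 (22.7% against 24.8%), Mcts2 (4.90% against 9.22%) and Slc38a4 (4.11% against 6.74%) were lower.

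Germline genes were close to PGC, with 8 of 17 members higher and 9 lower and medians of 21.8% in pESC-PGCLC and 23.2% in PGC (percentile 1.73, or 1.05 with matching to the nearest genes). Tdrd1, a piRNA pathway gene, was at 57.6% against 49.2%, Dpep3 at 59.3% against 54.4% and Sycp3, a meiotic chromosome axis gene, at 45.4% against 41.2%. Clustered protocadherins were lower at 18 of 25 members (percentile 0.02), with a difference of -5.22 points at Pcdhga2, which was at 17.7% in PGC. That percentile is against random lists of scattered genes, while members of this list are neighbours that can share a region. X-linked genes were lower, with a median of 1.84% against 2.32%, below all random lists. No island listed in all 5 libraries was 25 points higher in pESC-PGCLC (4 were among all islands common to these 2 libraries), and 3 short ones were lower, at Ocstamp (22.4% against 51.8%), within Kdm2b (15.4% against 43.4%) and within Rapgef2 (10.3% against 35.7%); only 1 of these was left without the islands listed at exactly 0 or 1 in some library. Promoters 25 points apart numbered 14 higher and 6 lower, or 10 higher and 10 lower with the overall shift taken out.

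The comparison of pESC-PGCLC with ESC-PGCLC asked whether the differences between the lines were present after induction. The maternally methylated members were higher in pESC-PGCLC at 11 of 12, 7 of them by at least 25 points, with medians of 38.7% and 6.75% (median difference 35.0 points, above all random lists). The widest gaps were at Airn (62.1% in pESC-PGCLC, 1.03% in ESC-PGCLC), Kcnq1ot1 (75.0% against 20.5%), Peg3 (58.8% against 12.2%), Zrsr1 (43.0% against 1.61%), Peg13 (74.2% against 33.0%) and Nap1l5 (53.4% against 14.5%). Plagl1 was at 22.7% against 2.47%, Gnasas1 at 21.1% against 6.18% and Nnat at 24.8% against 11.7%, and Slc38a4 was again lower, at 4.11% against 7.33%.

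All 12 islands at least 25 points apart were higher in pESC-PGCLC (14 higher and 3 lower among islands common to these 2 libraries). Of the 12, 11 lay at imprinted genes, among them islands within Gnas, Impact and Inpp5f, genes added after values were seen. The other was within Mid1 on the X chromosome (169986832 to 169987790, 38.2% against 11.3%). Of these 12 islands, 10 were also among the 14 that were higher in pESC than in female ESC, a comparison that shares no library with this one, where independent lists of those sizes would share 0.0118. Of the promoters, 17 of the 25 higher in pESC-PGCLC were among the 39 higher in pESC (0.0478 for independent lists), and 1 of the 23 lower was among the 54 lower in pESC (0.0609). The values for independent lists count every region as equally able to differ. However, 70.9% of promoters were at or under 20% in female ESC and could not be 25 points lower in pESC. The value for lower promoters is thus too small, and the others may be, so 1 shared promoter is no sign of an excess. At 10 points, 27 islands were higher and 51 lower. Germline genes were lower in pESC-PGCLC at 15 of 17 members (medians 21.8% and 30.4%, percentile 0.01, or 0.34 with matching to the nearest genes), and 77.5% of the CGIs with a mean of at least 30% were lower too. Sycp1 was at 21.8% against 32.5%, Tuba3a at 32.3% against 42.5%, Dpep3 at 59.3% against 69.2% and Mov10l1 at 53.3% against 63.2%. Pcdhb15, a protocadherin, was at 27.5% against 39.1%, and X-linked genes had medians of 1.84% against 1.63% (percentile 100). Promoters 25 points apart numbered 25 higher and 23 lower, or 26 higher and 14 lower with the overall shift taken out; at 10 points 113 were higher and 472 lower.

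Mean methylation was lower in ESC-PGCLC than in female ESC in each of the 8 region classes, although 42.7% of CGIs and 44.7% of 5' UTRs were lower, or 57.1% and 55.3% with the CHH level taken out. The mean over promoters was 17.2% in female ESC and 15.4% in ESC-PGCLC, and the mean over repeats 50.2% and 45.3%. The maternally methylated members had a median of 11.9% before and 6.75% after, with 9 of 12 lower and none by 25 points (median difference -1.14 points, percentile 58.8, or 98.7 with matching to the nearest genes). Peg3 had the largest difference, 36.2% in female ESC and 12.2% in ESC-PGCLC, followed by Gnasas1 (17.8% and 6.18%), Nap1l5 (22.8% and 14.5%), Peg13 (36.9% and 33.0%) and Nnat (15.1% and 11.7%); Kcnq1ot1 was at 16.7% and 20.5%. Of the germline genes, 15 of 17 were lower in ESC-PGCLC (percentile 3.07, or 84.7 with matching to the nearest genes), as were 89.3% of the CGIs with a mean of at least 30%. The lower members included Tdrd1 (65.4% and 54.3%), Hormad1 (23.6% and 15.7%) and Sycp3 (54.4% and 48.0%). Dnmt3l was at 39.0% in female ESC and 24.9% in ESC-PGCLC, and Pcdhb17 at 40.3% and 27.7%.

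Among islands listed in all 5 libraries, 1 was at least 25 points higher in ESC-PGCLC and 8 were lower, none at an imprinted gene. The higher one lay within Polrmt (62.6%, against 21.1% in female ESC). Among islands common to these 2 libraries 2 were higher and 10 lower. Of the 8 lower ones, 7 were no longer than 400 bp. The other was an island with Y chromosome coordinates that all 5 libraries list (90825140 to 90829322, 32.5% against 72.2%). Cells of a female line should hold no Y chromosome, so these levels cannot be read as methylation of the Y. The short ones included islands within Clstn2 (42.9% against 80.3%) and Lmtk3 (44.2% against 69.3%), at Ldoc1 (27.1% against 52.6%), and at chromosome 13, 119836757 to 119837075 (15.4% against 57.7%). Those within Clstn2 and on chromosome 13 were also called lower in pESC, against the same female ESC value. With the overall shift taken out 5 were lower. Promoters 25 points apart numbered 21 higher and 77 lower, or 23 higher and 33 lower with the shift taken out.

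Mean methylation was lower in pESC-PGCLC than in pESC in every region class except CGIs (3.59% against 3.55%), an exception that ended with the CHH level taken out (2.90% against 2.99%). Of CGIs 36.4% and of 5' UTRs 43.5% were lower, or 48.2% and 51.8% with the CHH level taken out. The mean over promoters was 15.9% in pESC and 14.6% in pESC-PGCLC, and the mean over repeats 46.3% and 43.2%. Imprinted members had medians of 41.0% and 38.7%, with 8 of 12 lower and none by 25 points (median difference -1.94 points, percentile 8.46). Gnasas1 was at 40.9% in pESC and 21.1% in pESC-PGCLC, Peg3 at 65.7% and 58.8%, Plagl1 at 28.7% and 22.7%, Peg10 at 39.1% and 34.3%, and Kcnq1ot1 at 67.7% and 75.0%. Germline genes were lower at 14 of 17 members (percentile 0.45, but 34.6 with matching to the nearest genes), as were 80.9% of the CGIs with a mean of at least 30%, with Tdrd1 at 68.4% and 57.6%, Dpep3 at 69.4% and 59.3% and Sycp1 at 28.3% and 21.8%. X-linked genes had a median of 1.49% in pESC and 1.84% in pESC-PGCLC (percentile 99.3), and 5 trophoblast genes 1.39% and 1.94% (percentile 96.7).

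Among islands, 1 was at least 25 points higher in pESC-PGCLC, within Rgl3 (29.0%, listed at 0 in pESC), and 4 were lower; among islands common to these 2 libraries 3 were higher and 4 lower. The lower ones included Sil1 (3.23% against 33.3%) and Gm16372 (24.5% against 49.5%), a gene model. Of the 4 lower islands, 3 were no longer than 400 bp. The other was the island at Y chromosome coordinates 90825140 to 90829322 (46.2% against 71.9%). Cells with no sperm genome should hold no Y chromosome, so here too the levels cannot be read as methylation of the Y. Leaving out islands at exactly 0 or 1 in any library, which removes Rgl3 and Sil1, left none higher and 3 lower. Promoters 25 points apart numbered 8 higher and 27 lower, or 9 higher and 14 lower with the shift taken out.

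The change on induction was then compared between the lines, as the difference of the pESC change and the female ESC change at each island and promoter. Of 14214 islands, 3 had a difference of changes of at least 25 points in the positive direction and 3 in the negative direction, none of them at an imprinted gene. Of 20388 promoters, 67 had a difference of changes of at least 25 points in the positive direction and 50 in the negative direction. At 40 points these counts were 17 and 12. In the simulation of single comparisons, counting error alone called between 43 and 55 unchanged promoters at 25 points. The difference of changes was not simulated, so how many of its promoters counting error would give is unknown. The island within Polrmt had a change of 41.6 points from female ESC and -1.71 points from pESC, and Sil1 -1.37 and -30.1 points. The island within Speg, a muscle kinase gene, had changes of -23.8 and 12.2 points, and that at chromosome 13, 119836757 to 119837075, -42.3 and -2.84 points. The chromosome 13 island was at 57.7% in female ESC and between 4.70% (PGC) and 15.4% (ESC-PGCLC) in the other libraries. Sil1 was at 33.3% in pESC and between 0 (PGC) and 3.23% (pESC-PGCLC) in the others. The differences at Sil1 and on chromosome 13 thus rest largely on 1 library each. Differences of changes were not tested, with 1 library at each point.

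Regions listed as paternally methylated were measured at Rasgrf1 and, in part, at Meg3. The shore at chromosome 9, 89877672 to 89879672, upstream of Rasgrf1, a guanine nucleotide exchange factor gene, was at 57.9% in female ESC, 47.6% in ESC-PGCLC, 38.7% in pESC, 27.9% in PGC and 21.7% in pESC-PGCLC. Since pESC hold no sperm genome, the levels of this shore in pESC and pESC-PGCLC cannot come from a paternal allele. The shore in the intergenic region upstream of Meg3 (chromosome 12, 109528472 to 109530473) was listed in 4 libraries, at 28.6% in ESC-PGCLC, 9.38% in PGC, 4.76% in pESC-PGCLC and 0 in pESC.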

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

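All tests in this part were chosen after the results were seen, except the count of Y chromosome repeat entries. Differences between the lines below were not tested, since each library stands alone. On induction the island within Polrmt changed by 41.6 points from female ESC and -1.71 points from pESC, a difference of changes of -43.3 points. This 280 bp island was at 21.1% in female ESC and between 42.8% (PGC) and 62.6% (ESC-PGCLC) in the other libraries. The difference thus rests largely on the low female ESC value. The island at Gm5522, a gene model, changed by 10.5 and -16.8 points (difference -27.3 points), and the island within Speg by -23.8 and 12.2 points (difference 36.0 points). The Speg island was at 54.4% in female ESC and between 29.5% (pESC) and 41.6% (pESC-PGCLC) in the other libraries. The mean over all islands changed by -0.237 points from female ESC and 0.0354 points from pESC, a difference of 0.272 points; with the CHH level taken out both changes were negative, at -0.372 and -0.0848 points.

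On the Y chromosome, 5 of 7 CGIs and shores were listed in the PGC library alone, against 763 of all 176303 CpG entries, and these 5 entered no comparison.

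The first pattern is that maternally methylated imprinted regions of the PGC library, with a median of 34.1%, lay near pESC (41.0%) and far above female ESC (11.9%). Incomplete conversion is argued against by the CHH level of islands, 0.071 points above female ESC where the imprinted gap was 22.2 points. A wrong label, with the PGC library being a pESC or pESC-PGCLC library, cannot be told apart from the stated origin by the Y chromosome: 4 of the 5 Y regions found in PGC alone lie between Y regions that all 5 libraries list, leaving 1 outside that span, and Y repeat entries in PGC exceeded those of the closest pESC library by 1. A candidate explanation is that the sorted fraction held cells with an inactive X chromosome. Islands of the X under 5% in female ESC had a mean of 2.38% in PGC, at percentile 100 of random autosomal sets. Their mean was 1.92% in pESC-PGCLC (percentile 96.3), 1.70% in ESC-PGCLC (percentile 6.70) and 1.52% in pESC (percentile 1.52). Shores under 5% in female ESC had X means of 3.34% in PGC and 3.22% in pESC-PGCLC, against 2.76% and 2.91% on autosomes. In ESC-PGCLC these were 2.85% against 2.78%, and in pESC 2.24% against 2.69%. On shores the X excess was thus not confined to the sorted fetal cells. Autosomal islands under 5% in female ESC had a mean of 1.62% in PGC, so the X excess was small beside the imprinted gap of 22.2 points. The percentile gives rank only, and whether that excess is large enough for the explanation was not tested. The X values do not show that such cells carried the imprints or which cells they were. The sex of the fetuses is not given in the sources used here, and the SSEA1 sort should remove gonadal somatic cells. Germ cells that had kept their imprints at stage E12.5 stay open as well. In biparental cells of either kind, kept imprints alone would methylate at most 1 allele of each pair. In PGC, Peg13 (63.2%) and Kcnq1ot1 (61.7%) were above the level that gives, while the median of the members, 34.1%, was below it. Kept imprints alone thus do not account for Peg13 and Kcnq1ot1.

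The second pattern is that 11 of 12 imprinted members were lower in female ESC than in pESC, and in ESC-PGCLC than in pESC-PGCLC, Slc38a4 being the exception. Female ESC nevertheless had the highest mean in each of the 8 region classes. Low methylation across the whole library is argued against by matched islands, where the median difference was -1.44 points (pESC minus female ESC; -4.06 points with the nearest genes), and regions read few times by the separate pair of induced libraries, in which all 8 members 25 points lower in female ESC were at least 10 points lower too. The number of maternal genomes, 2 in pESC and 1 in female ESC, would alone give a ratio near 0.5 if maternal alleles were equally methylated in both lines. In pESC itself the median was 41.0% and the highest member 77.8%, short of full methylation of 2 maternal genomes. Loss of methylation in pESC was not tested. The PGC library, labelled as primordial germ cells, a label that could not be checked, had a median ratio to pESC of 0.849. At Peg10, Zrsr1, Airn and Plagl1, the members with a ratio under 0.2, the ratio of ESC-PGCLC to pESC-PGCLC was at most 0.109. That is below what the number of maternal genomes alone would give. For the other 8 members, with medians of 0.455 (female ESC to pESC) and 0.288 (the induced pair), it cannot be told apart from loss of imprints in the female line, since each origin has 1 line, and Slc38a4 among them, with ratios of 2.30 and 1.78, follows neither; loss at Airn and its like in that line is a hypothesis that may be checked in other lines.

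The third pattern is the order of mean methylation by region class, highest in female ESC and lowest in PGC. Conversion is argued against by the CHH level of promoters, which was 0.078 points higher in PGC than in female ESC. Different sets of regions do not enter, since the means were taken over regions listed in all 5 libraries. Over these common promoters the difference was -3.45 points (PGC minus female ESC). Cell type, line, culture and library differ together between these groups, so which of them sets the order stays open.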

How the results depend on the processing

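Alternatives with the CHH correction, with regions at exactly 0 or 1 left out, with the overall shift taken out, with other imprinted members or with matching on length or on the nearest genes were chosen after seeing the data. The median differences of the imprinted members stayed within their bootstrap intervals under all 3 alternatives run on them; with all 10 further regions added (22 members) they were 28.4 points for pESC against female ESC, -20.6 for ESC-PGCLC against PGC and 25.6 for pESC-PGCLC against ESC-PGCLC. The CHH correction turned 3 differences of class means: CGIs at -0.085 points for pESC-PGCLC against pESC and -0.030 for ESC-PGCLC against pESC, and 5' UTRs at -0.125 for the latter pair. Mean promoter levels kept their order. Over all promoters listed in each library they were 17.3% in female ESC and 16.7% in pESC, a narrower gap than over common promoters. The others were then at 14.5% in PGC, 16.3% in ESC-PGCLC and 15.5% in pESC-PGCLC. The CHH correction gave 16.7% in female ESC, 15.4% in pESC, 13.2% in PGC, 14.8% in ESC-PGCLC and 14.0% in pESC-PGCLC. The cause was not tested where not stated; looser and stricter thresholds change counts by construction.

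At 10 points, islands higher and lower numbered 27 and 128 for pESC against female ESC, 114 and 43 for ESC-PGCLC against PGC, 27 and 26 for pESC-PGCLC against PGC, 27 and 51 for pESC-PGCLC against ESC-PGCLC, 8 and 135 for ESC-PGCLC against female ESC, and 10 and 48 for pESC-PGCLC against pESC. In the same order, promoters numbered 222 and 1027, 1108 and 100, 399 and 116, 113 and 472, 164 and 1350, and 119 and 703. At 40 points, islands numbered 4 and 1, 0 and 2, 0 and 0, 6 and 0, 1 and 2, and 0 and 0. Differences of the induction changes at islands numbered 0 positive and 1 negative at 40 points, from 3 and 3.

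With islands common to the 2 libraries, counts moved to 5 higher (ESC-PGCLC against PGC), 4 higher (pESC-PGCLC against PGC), 3 lower (pESC-PGCLC against ESC-PGCLC), 2 higher (ESC-PGCLC against female ESC) and 3 higher (pESC-PGCLC against pESC), as more islands enter. Without regions at 0 or 1, 1 island was lower for pESC-PGCLC against PGC and 0 were higher for pESC-PGCLC against pESC. With the overall shift taken out, islands lower numbered 1 (pESC against female ESC) and 5 (ESC-PGCLC against female ESC); promoters lower numbered 30, 10 (pESC-PGCLC against PGC), 14 (pESC-PGCLC against ESC-PGCLC), 33 (ESC-PGCLC against female ESC) and 14 (pESC-PGCLC against pESC), and 15 were higher for ESC-PGCLC against PGC. With autosomes only, all 12 island counts stayed within 1.5 times. With matching on length, 3 of 78 list percentiles moved outside the central 95%: germline genes (1.09) and X-linked genes (2.07) for ESC-PGCLC against female ESC, and trophoblast genes (97.6) for pESC-PGCLC against pESC. With each member matched to the 50 genes nearest in mean methylation, germline genes moved inside it for pESC against female ESC (26.9), ESC-PGCLC against PGC (91.6) and pESC-PGCLC against pESC (34.6), as methylated genes were then compared with genes of like level. For ESC-PGCLC against female ESC, imprinted members (98.7), primed epiblast genes (1.22) and X-linked genes (2.04) moved outside it.

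Coverage minimums of 5 and 20 reads, pooled reads, the 99th percentile of coverage, 500 bp windows, thinning to 10 reads, the shorter promoter, means of site levels and matching on CpG number were not run, since the values used hold no reads or sites. Depth is unknown, so what it limits was not measured. Female ESC listed the fewest CpG entries (157458). Of its repeat entries, 0.433% were at exactly 100%, against 0.0236% to 0.0686% in the other libraries, and 1.53% at exactly 0, against 0.590% to 0.894%. Whether fewer reads lay behind this cannot be told without counts, so comparisons with female ESC may be less certain than the others.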

Other observations

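Repeat families differed in how much of their methylation separated PGC from female ESC. The highest ratios of the 89 families with at least 100 entries were in retroviral families: IAPEz-int, the intracisternal A particle, had a mean of 75.6% in female ESC and 68.5% in PGC, a ratio of 0.906 over 328 entries, IAPEY3-int a ratio of 0.904 and MMERVK10C-int 0.893. Among LINE/L1 families, ratios lay between 0.761 (L1MdV_III, 47.3% and 35.9%) and 0.860 (L1MdN_I, 42.9% and 36.9%), with L1MdA_I at 69.4% and 59.4% (ratio 0.856) and L1MdTf_I at 43.3% and 36.1% (ratio 0.834). The lowest ratios were at MLT1C2, a MaLR element, with 48.2% and 35.5% (ratio 0.737), L2c with 44.0% and 32.4% (ratio 0.737) and MER5A with 44.9% and 33.4% (ratio 0.742). IAPEz-int was at 73.3% in ESC-PGCLC and 70.9% in pESC-PGCLC, between female ESC and PGC, while L1MdTf_I (35.5%) and L1MdTf_II (35.0%, against 35.5% in PGC) were lower in pESC-PGCLC than in PGC.

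The following test was chosen after the values were seen. A single proportional loss for every repeat family would leave the ratio unrelated to the starting level. Across these families, Spearman's rho between the ratio and the female ESC level was 0.481, and 0.551 with the pESC level, which shares no library with the ratio; families are not independent replicates. One factor for all families is argued against. The ratio tended to be higher in the more methylated families, and the cause was not tested.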
